A study of Drosophila melanogaster with 8 samples.

How the data were processed

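Heads of Canton-S flies were compared after a light pulse and without one, with 4 arrays per group. Per the labels' protocols, total RNA was extracted with Trizol, labelled with biotin by an Affymetrix in vitro transcription kit and hybridised to Affymetrix arrays. The authors deposited 1 table of log2 values, 1 per probe set and array. The log2 scale was read from the values, which stay just under the limit of a 16-bit scanner on that scale. How the authors summarised probes, corrected the background and normalized the arrays is not given in the sources used here. Array medians between 2.95 and 3.07 fit values already brought to a common scale, so the deposited log2 values were used as they are.

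The table holds 18952 probe sets, of which 183 control probe sets were left out and 18769 were tested. Gene names came from the platform annotation given with the values, in which 13647 probe sets have 1 symbol, 402 have several and 4903 are not listed. Symbols of 13544 were updated through their gene number in the NCBI RefSeq table of assembly Release 6 plus ISO1 MT, which was used for names only. No gene was named from a probe set with several symbols, and the named probe sets stand for 11982 genes. A list member written with a current symbol was never read as an older name of another gene, a rule added after the data were seen that changed no list call.

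Groups and replicate numbers were taken from the labels. Pulsed and unpulsed arrays were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05 on adjusted p. Probe sets with low values were kept. Core clock genes were also adjusted over the list alone and given an exact two-sided permutation test over 70 arrangements. Members of every other list were likewise adjusted over their list alone, separately for each list and without correction for the number of lists. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over all 38 lists, of which 27 address biological questions and 11 hold markers of cell types, tissues or sex. Each gene was represented by its probe set with the highest mean over all 8 arrays, lists needed 3 measured members, and 795 list genes were measured. fry and camera with an estimated correlation stood beside it. Control probe sets for actin, GAPDH and eIF-4a gave a 3′ minus 5′ log2 difference per array, compared by exact permutation tests. No pair of arrays held identical values, and the smallest SD of a difference between a pair of arrays was 0.166 log2 units.

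Tests, lists, alternatives and the rule for named genes were fixed before the data were examined. That rule takes the 12 genes with the highest and the 12 with the lowest moderated statistic among probe sets with 1 symbol, those past the threshold first and then the next by unadjusted p. It adds the 8 core clock genes and up to 4 members of each list with the smallest unadjusted p. These were carried through every alternative, except that 11 dim list members are absent from the 2 fits with the filter on dim probe sets, and the text gives a choice of them with values, made after the values were seen. Members of the tissue and sex lists named by their values on single arrays, such as SP and Acp53Ea, were also chosen after their values were seen.

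Alternatives tried were quantile normalization, median-centred arrays, a pseudocount of 16 on the linear scale, a filter leaving out probe sets below the 40th percentile of mean value (11261 were left), a trended and robust spread, array weights, the replicate number as a block and each array left out in turn. Other thresholds were an adjusted p of 0.1, an unadjusted p of 0.05 and a 1.5-fold change, and other list tests were those above and the mean of a gene's probe sets. Another 5 alternatives were added after seeing the data. Left out were pulsed replicate 2 with the filter and, separately, with the trended spread, and added to the fit were a batch term for replicates 1 and 2 against 3 and 4, a yolk protein covariate and the mean 3′ minus 5′ difference as a covariate.

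The steps were tested on simulated data in 20 simulations of 4 against 4 arrays with 18769 probe sets, 200 of them changed and drawn from those above the filter. Recovery was 52.1% at a log2 change of 0.5, 84.9% at 1 and 97.4% at 2, and 6.78% of the calls were unchanged probe sets. A clock list shifted by -0.3 was called in 20 of 20 simulations, and 0.05 unchanged lists were called on average. The simulated probe sets vary independently, so the list figures leave out correlation between genes. The adjustment is stricter where fewer probe sets change, and recovery was simulated only with 200 changed. These percentages therefore do not give the power for data in which few probe sets change.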

Results

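Light during the night resets the circadian clock of Drosophila, and the experiment asked which transcripts of the fly head differ after such a pulse. Flies of Canton-S, a wild-type laboratory strain, were 3 to 5 days old and had spent 4 days at 25 °C with 12 h of light per day. Pulsed flies received 30 min of saturating light from ZT 15 (zeitgeber time, in hours after lights on), when they had been in darkness for 3 h. They were frozen 1 h after it, at ZT 16.5, and unpulsed flies were sampled at the same time. Total RNA of heads was measured on 8 Affymetrix expression arrays, 4 per group, with log2 values for 18769 probe sets besides the controls. Array medians lay between 2.95 and 3.07 log2 units, and the number of arrays limits the precision. Correlations between arrays, across probe sets, ran from 0.995 to 0.998 among 7 of the arrays, and from 0.985 to 0.988 between pulsed replicate 2 and the others. The labels do not say that the replicates came from separate groups of flies, so each p measures only the spread between these samples, part of which can be technical. The yolk protein gene Yp1 was at 5.15 and 5.21 on 2 pulsed arrays and at 11.4 and 12.5 on the others. Among unpulsed arrays it was at 4.82 on 1 and at 11.3 to 12.7 on the rest, and Yp2 and Yp3 separated the same arrays. This argues against a single RNA pool per group, but arrays with like values could still share one.

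No probe set differed between pulsed and unpulsed heads at an adjusted p of 0.05. The genes described first had the strongest statistics and were picked for them. That their groups do not overlap is therefore no further support. subdued, which encodes a calcium-activated chloride channel of the anoctamin family, was lower in pulsed heads by a log2 difference of -0.37 (SE 0.028, n = 4 per group), with all 4 pulsed arrays below all 4 unpulsed ones. CG10513 was 2.76-fold higher, with a log2 difference of 1.46 (SE 0.13) and all 4 pulsed arrays above the unpulsed ones. Other high values belonged to eEF1gamma, a subunit of a translation elongation factor (0.26), TyrRS, the tyrosyl-tRNA synthetase (0.29), and ORMDL, a regulator of sphingolipid synthesis (0.20). Low values belonged to sug, a sugar-responsive transcription factor (-0.84), Hrs, an endosomal sorting protein (-0.30), Gprk1, a receptor kinase (-0.24), and cta, a G protein subunit (-0.33).

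With limma, 0 of 18769 probe sets passed an adjusted p of 0.05, and the smallest adjusted p was 0.0611, for subdued. At an adjusted p of 0.1 there were 2, subdued and CG10513 (adjusted p = 0.0942). At an unadjusted p of 0.05 there were 902, of which 450 were higher and 452 lower in pulsed heads, where chance alone gives 938. The groups did not overlap for 480 probe sets, 2.56% of those tested, against 2.86% by chance. The 24 genes with the strongest statistics, 12 in each direction, had adjusted p from 0.0611 to 0.539. CG10513 was the only call (adjusted p = 0.0259) with a trended and robust spread. With array weights, which rested mostly on pulsed replicate 3 (weight 6.81) and unpulsed replicate 2 (10.1), 2936 probe sets passed. Over all 20 refits the count ran from 0 to 2936.

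**Figure D1:**
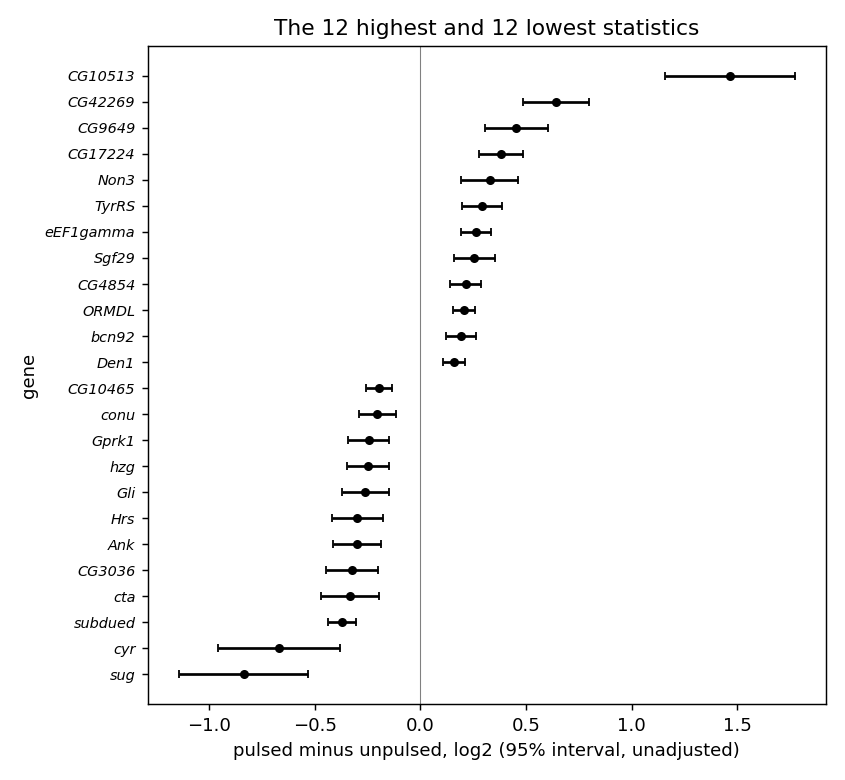
Difference between pulsed and unpulsed heads (log2, horizontal axis) for the 12 genes with the highest and the 12 with the lowest moderated statistic; points are the differences of 4 against 4 arrays and bars their unadjusted 95% intervals. CG10513 has the highest difference, 1.46, and sug the lowest, -0.84, and none of the 24 passed an adjusted p of 0.05.

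Transcripts of the core clock loops lay lower in pulsed heads as a list, with 7 of 8 below their unpulsed mean and a median log2 difference of -0.20. The largest difference was that of per, the repressor of the central feedback loop, at -0.49 (SE 0.12, n = 4 per group). vri, a repressor of Clk transcription, followed at -0.31 (SE 0.090), and all 4 pulsed arrays were below all 4 unpulsed ones for both genes. cwo, another transcriptional repressor of the loop, was at -0.30 (SE 0.14) and tim, the partner of per, at -0.22 (SE 0.11). Pdp1 (-0.17), cyc (-0.10) and Clk (-0.064) had smaller differences that hung on single arrays, and cry, the blue-light photoreceptor of clock neurons, was at 0.11. Pdp1 was at -0.32 without unpulsed replicate 3 and at -0.078 without unpulsed replicate 2, cyc at -0.027 without that array, Clk at -0.023 without pulsed replicate 2, and tim at -0.14 without unpulsed replicate 1.

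The list was called by camera (adjusted p = 0.00525), in a range of 2.5e-04 to 0.364 over 23 alternatives. The call was lost with an estimated correlation (0.080 against the preset 0.01), at an adjusted p of 0.364, and with fry's directional test, at 0.268. Other lists share both values through the adjustment, so neither is the evidence of this list alone. Of the 8 genes, 0 passed limma's test over all probe sets, and per (adjusted p = 0.0320) and vri (adjusted p = 0.0452) passed when adjusted over the list alone. That adjustment was made within each of the 38 lists on its own and does not correct for their number. The exact permutation test gave each of those 2 genes p = 0.0286, the smallest that 70 arrangements can give, and p = 0.114 after adjustment over the list. With only 2 of 8 genes at that floor the adjusted value cannot fall under 0.05, so it decides nothing. No clock gene passed over the list alone without pulsed replicate 2, without pulsed replicate 4, or without unpulsed replicate 1, 2 or 3, and 1 passed without pulsed replicate 1. Of 20 refits, per passed over the list alone in 11 and vri in 7, and the list median was -0.12 without unpulsed replicate 1. The second probe sets differed from the first for tim (0.12) and less so for cwo (-0.45). Among replicates numbered 1 and 2 the differences were -0.53 for per, -0.38 for vri, -0.60 for cwo and -0.50 for Pdp1. Among replicates 3 and 4 they were -0.45, -0.23, 0.0073 and 0.15 for the same genes. The array's own GAPDH control, a sign of RNA integrity, moved with the groups too: its 3′ minus 5′ log2 difference was 0.857 in pulsed and 1.03 in unpulsed heads (exact permutation p = 0.0286).

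**Figure D2:**
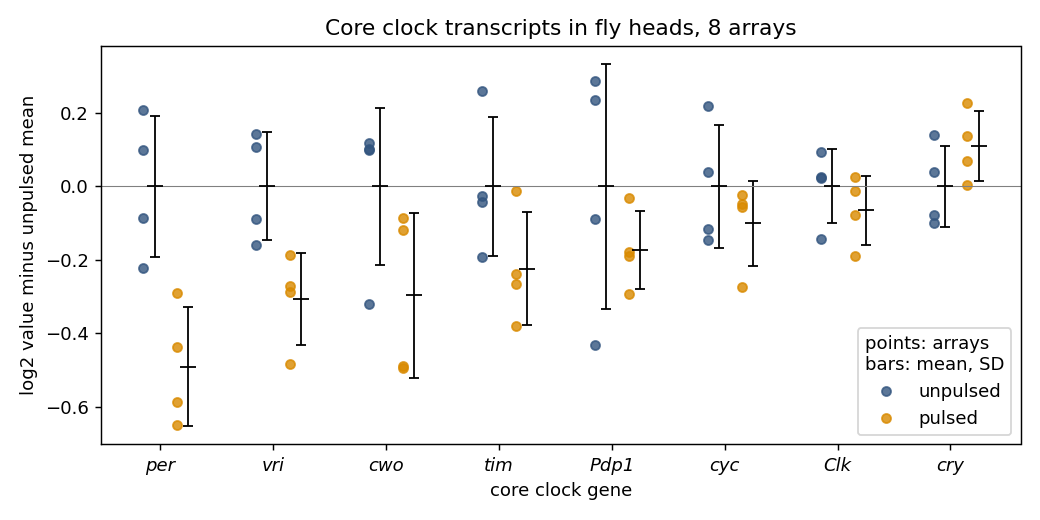
Log2 value of the 8 core clock genes on each array, minus the unpulsed mean of that gene; points are arrays, and bars the mean and SD of 4 arrays. For per and vri all pulsed arrays lie below all unpulsed ones, with mean differences of -0.49 and -0.31.

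Genes that modify or degrade clock proteins, with the output neuropeptide and its receptor, were not called as a list (median -0.057, camera adjusted p = 0.294). The values of slmb and jet, which serve the degradation of per and tim proteins, were -0.25 and -0.12, with slmb at -0.14 without unpulsed replicate 1 and jet at -0.065 without pulsed replicate 4, and 0 of 13 members passed over all probe sets or over the list alone. Head transcripts known to cycle had members on both sides: CG9649 was at 0.45 (adjusted p = 0.00221 over the list alone), Ugt35B1 at 0.34 (0.0254) and Achl at -0.50 (0.0294). Those 3 of 13 passed when adjusted over the list alone, which does not correct for the number of lists, and 0 over all probe sets. Refits reuse the same arrays, so counts of refits passed are not separate support. CG9649 passed over the list alone in all 20 refits, Ugt35B1 in 15 and Achl in 10, and without pulsed replicate 2 Achl did not (limma adjusted p = 0.0867, in a range of 3.3e-04 to 0.0913). For the list as a whole the median of 0.0068, which turned negative with median-centred arrays, was not called (camera adjusted p = 0.762). Hr38, a nuclear receptor gene induced by neuronal activity, was at 0.89 (SE 0.19) with all 4 pulsed arrays above the unpulsed ones. It was the 1 of 17 activity-regulated genes that passed over the list alone (limma adjusted p = 0.0440), with 0 over all probe sets, it passed over the list alone in 9 of 20 refits, and its other probe set was at 0.057. Its signal was low, with a mean of 3.02 log2 units in unpulsed heads, and with a pseudocount of 16 the difference was 0.37 and did not pass (adjusted p = 0.108 over the list alone, in a range of 0.00263 to 0.313). The activity-regulated list itself was not called (median 0.067, camera adjusted p = 0.314).

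Among genes of fasting and lipid mobilisation, sug was at -0.84 (SE 0.13) and the lipase gene Lip4 at 0.39 (SE 0.075). These 2 of 14 passed limma's test when adjusted over the list alone (adjusted p = 0.00490 and 0.00889), and 0 over all probe sets, and over the list alone sug passed in all 20 refits and Lip4 in 18. The list did not move on balance (median 0.015, camera adjusted p = 0.676). fry's test for change in either direction called 5 lists, those of fasting and lipid mobilisation (adjusted p = 0.00136), cycling head transcripts (0.00265), immune recognition (0.0291), oxidative stress (0.0291) and core clock loops (0.0422). Without pulsed replicate 2 that test gave the fasting and the cycling lists an adjusted p of 0.0146 each, the activity-regulated list the same value (0.0802 with all arrays), and the immune, oxidative and clock lists 0.140, 0.477 and 0.392.

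Immune recognition and signalling genes were higher in pulsed heads as a list, with 15 of 18 above the unpulsed mean and a median of 0.14. PGRP-LB, a peptidoglycan-degrading regulator of the immune deficiency pathway, had a log2 difference of 0.77 (SE 0.14, n = 4 per group), key, a kinase subunit of that pathway, 0.16 (SE 0.038), and the receptor gene Tl -0.29 (SE 0.090). Camera called the list (adjusted p = 4.8e-05), with an adjusted p = 0.364 with an estimated correlation and a range of 4.7e-07 to 0.490 over 23 alternatives. Over all probe sets 0 members passed, and PGRP-LB (limma adjusted p = 0.0170) and key (0.0324) passed when adjusted over the list alone. Without pulsed replicate 2 key did not pass there (limma adjusted p = 0.105, in a range of 0.00155 to 0.336), and of 20 refits PGRP-LB passed in 16 and key in 5. With array weights the list median was 0.078 and the call ended. Antimicrobial peptide genes, targets of these pathways, had a median of 0.54, with CecB at 1.27 (SE 0.62) and Mtk at 0.60 (SE 0.35), and 7 of 8 above the unpulsed mean. That list was called by camera (adjusted p = 0.0320), with an adjusted p = 0.879 with an estimated correlation, and 0 members passed over all probe sets or over the list alone. With array weights the median was -0.50 and the list was called in the opposite direction (adjusted p = 0.0140, in a range of 1.8e-05 to 0.879 over 23 alternatives). The call ended without pulsed replicate 2 or 4 and without unpulsed replicate 1, 3 or 4 (adjusted p from 0.0546 to 0.379). Without unpulsed replicate 3 its median was 0.25 and Mtk at 0.36, without pulsed replicate 2 the median was 0.37, and CecB and Mtk were negative with array weights (-0.54 and -0.46).

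Genes of the oxidative stress response were also higher as a list, with 15 of 19 above the unpulsed mean and a median of 0.11. The glutathione transferase genes GstE1 (0.36, SE 0.11), GstE3 (0.25, SE 0.080) and GstD2 (0.22, SE 0.068) led it, and Gclm, of glutathione synthesis, was at -0.20 (SE 0.071). Camera called it (adjusted p = 0.00233), with an adjusted p = 0.364 with an estimated correlation and a range of 3.7e-04 to 0.497 over 23 alternatives, and 0 members passed over all probe sets or over the list alone. The 3′ minus 5′ difference of the GAPDH, eIF-4a and actin controls, averaged, was 2.39 in pulsed and 2.62 in unpulsed heads (exact permutation p = 0.0857). With that average as a covariate the medians were 0.0069 for oxidative stress and 0.00032 for immune recognition, and no list was called. Without pulsed replicate 2 the clock, oxidative stress and immune lists were the 3 that camera called, with medians of -0.18, 0.090 and 0.11, and with an estimated correlation none of them was called there (adjusted p = 0.418 each).

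Genes of the eye were lower in pulsed heads in 2 lists. Phototransduction genes had 16 of 22 members below the unpulsed mean and a median of -0.082, led by Calx, the sodium-calcium exchanger (-0.37, SE 0.082), Cds, of phosphoinositide recycling (-0.19, SE 0.055), and Pis, the phosphatidylinositol synthase gene (-0.18, SE 0.059). Eye pigment genes had 11 of 14 below and a median of -0.11, with the pigment transporter gene bw at -0.26 (SE 0.076) and cm, of vesicle traffic to pigment granules, at 0.14 (SE 0.068, and 0.081 without pulsed replicate 2). Camera called both lists (adjusted p = 0.0189 and 0.0417), with adjusted p = 0.879 and 0.364 with an estimated correlation, and 0 members of either passed over all probe sets or over the list alone. Without pulsed replicate 2, whose RNA stood apart, both had an adjusted p of 0.0814, with medians of -0.051 and -0.081. The phototransduction call also ended without pulsed replicate 3 or unpulsed replicate 1 or 3, and that of eye pigment without any array but unpulsed replicates 2 and 3. Without unpulsed replicate 3 the phototransduction median was -0.030, and that of eye pigment was -0.071 without unpulsed replicate 1 and -0.073 without unpulsed replicate 2. With array weights the phototransduction median turned positive (0.0069), that of eye pigment was -0.022, and neither list was called. The 3′ minus 5′ covariate also ended both calls, with medians of -0.070 and -0.080.

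Neurotransmitter receptor genes had 23 of 31 members lower and a median of -0.035, with the serotonin receptor gene 5-HT2A at -0.25 (SE 0.069) and the nicotinic receptor gene nAChRalpha4 at -0.62 (SE 0.35), which was -0.32 without pulsed replicate 2 and 0.17 with the 3′ minus 5′ covariate. The list was called (camera adjusted p = 0.0367), with an adjusted p = 0.879 with an estimated correlation and 0.980 without unpulsed replicate 1, and the call also ended without pulsed replicate 2 or 3 or unpulsed replicate 2. Its median ran from -0.15 without unpulsed replicate 3 to -0.0058 without unpulsed replicate 1, with -0.12 without pulsed replicate 1 or unpulsed replicate 4 and -0.061 without unpulsed replicate 2. Neuron markers had a median of -0.16 and were not called (camera adjusted p = 0.249), and their median was -0.027 without unpulsed replicate 1. Receptor transcripts relative to the share of neurons were not tested. Cytosolic ribosomal protein genes had 22 of 34 members higher and a median of 0.027, led by RpL3 (0.11, SE 0.025) and RpL34a (0.26, SE 0.061). Respiratory chain genes had 51 of 72 higher and a median of 0.039, with the complex I gene ND-18 at 0.19 (SE 0.056) and the cytochrome oxidase gene COX7B at -0.11 (SE 0.039). Camera called both (adjusted p = 0.0276 and 0.00525), with an adjusted p = 0.879 for each with an estimated correlation. Without pulsed replicate 2 the ribosomal list had a median of 0.011 (adjusted p = 0.716) and the respiratory chain list 0.0031 (0.899), and neither was called without unpulsed replicate 1. The ribosomal call also ended without unpulsed replicate 2 (median 0.011) or 4, and its median was 0.018 without unpulsed replicate 1, while that of the respiratory chain was 0.061 without pulsed replicate 4. With the 3′ minus 5′ covariate the respiratory chain median turned negative (-0.033), the ribosomal one was 0.0083 and that of the receptors -0.21, and 0 of the 3 lists were called. In these 3 lists 0 members passed over all probe sets or over the list alone, and the GAPDH control's 3′ minus 5′ difference moved with the groups here as well, 0.857 against 1.03.

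Stress and signalling genes outside those lists were not called as lists. The heat shock factor gene Hsf was at -0.12 (SE 0.035) and its target Hsp26 at 0.41 (SE 0.18), with a list median of -0.0082 and a mean of 0.055 (camera adjusted p = 0.967). CrebB, a cyclic AMP-responsive transcription factor, was at 0.55 (SE 0.21) with a mean of 2.83 in unpulsed heads, below the array medians, and at 0.21 with a pseudocount of 16 and 0.12 with the 3′ minus 5′ covariate. It belongs to a signalling list with a median of -0.058 (adjusted p = 0.294). The detoxification genes Cyp9b2 and Cyp6a8 were at 0.24 (SE 0.044) and 0.29 (SE 0.087), while the cytochrome P450 list had a median of 0.0017 (adjusted p = 0.307) that turned negative with median-centred arrays. UDP-glycosyltransferases had a median of -5.4e-04 and a mean of 0.022 (adjusted p = 0.508), and the median turned positive with quantile normalization. The DNA damage kinase gene lok was at 0.17 (SE 0.071) and photolyase and repair genes at a median of -0.0055 (adjusted p = 0.950). Medians of JNK and AP-1 targets (-0.015, adjusted p = 0.453), EGFR and ERK feedback genes (-0.0098, 0.853) and Turandot and JAK-STAT genes (-0.013, 0.307) were not called, nor were Notch targets (-0.016, 0.249). Leaving out single arrays changed the sign of the median of each of these 9 lists or moved it by over 1.5 times, and the signalling list with CrebB was called without unpulsed replicate 3 (-0.14) or 4 (-0.085). 0 of the members of these lists passed over all probe sets or over their list alone.

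Genes of neuronal output were likewise not called. The neuropeptide genes AstC and sNPF were at -0.22 (SE 0.060) and -0.36 (SE 0.15, and -0.23 without pulsed replicate 2 for sNPF), with a list median of 0.029 (camera adjusted p = 0.973). Potassium, sodium and calcium channel genes had a median of -0.048 (0.277), with the potassium channel gene Sh at -0.59 (SE 0.33, and -0.38 without unpulsed replicate 1). Ecdysone response genes had a median of -0.0072 (0.249), with the nuclear receptor gene Hr3 at -0.38 (SE 0.13). Proteasome genes, with Rpn11 at 0.14 (SE 0.039), had a median of 0.0030 (0.195) that turned negative with median-centred arrays, and cuticular protein genes one of -0.0027 (0.667). Single arrays moved each of these 5 medians by over 1.5 times: that of ecdysone response was -0.10 without unpulsed replicate 3, and without that array channel (-0.092) and proteasome genes (0.019) were called. 0 members of these 5 lists passed over all probe sets or over their list alone, so that of the 27 lists on biological questions camera called 9, of 38 lists in all 11, and 0 with an estimated correlation or with fry's directional test, beside the 5 of its test in either direction. At an unadjusted p of 0.05 camera, camera with an estimated correlation and fry's directional test gave 12, 4 and 4 lists.

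Markers of cell types and tissues showed which RNA the head samples held. Transcripts of testis and accessory gland had a median difference of 0.98 and those of gut digestive enzymes 0.45, and both lists were called by camera (adjusted p = 0.00676 and 0.0458), with an adjusted p = 0.879 for each with an estimated correlation. Both rest on pulsed replicate 2: the sex peptide gene SP had a log2 value of 8.16 there and of 2.19 to 2.21 on the other arrays, the accessory gland gene Acp53Ea 9.94 there, and the trypsin gene alphaTry 8.60. Without that array the medians were 0.0027 and 0.0046, and the gut call also ended when any 1 unpulsed array was left out. Lists of neurons (median -0.16, adjusted p = 0.249), glia (-0.017, 0.261), fat body (-0.0045, 0.728), antennal and gustatory support cells (-0.063, 0.0717) and muscle (0.050, 0.249) were not called. Without unpulsed replicate 3 the lists of neurons (-0.16), glia (-0.043) and antennal support cells (-0.073) were called, as was the last without pulsed replicate 1 (-0.053) and muscle without unpulsed replicate 1 (0.10). Haemocytes (-0.025, 0.840), ovary and eggshell (-0.013, 0.453) and male-biased head transcripts (-5.2e-04, 0.803) were not called with all arrays either. 0 marker genes passed over all probe sets or over their list alone, including onecut of neurons (-0.48, SE 0.12), nrv2 of glia (-0.37, SE 0.12), Mlp84B of muscle (0.23, SE 0.055) and Obp69a of the antenna (-0.88, SE 0.34).

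Yolk protein transcripts, made by the female fat body, separated the arrays within both groups. Yp1 had log2 values of 4.82, 5.15 and 5.21 on unpulsed replicate 1 and pulsed replicates 3 and 4, and of 11.3 to 12.7 on the other 5 arrays. The female-biased list had a median of -1.33 and was not called (camera adjusted p = 0.762). It ran from -2.69 without unpulsed replicate 1 to -0.39 without pulsed replicate 3, and with array weights it was -4.83 and the list was called (adjusted p = 0.00741, in a range of 0.00741 to 0.985). The mean of Yp1, Yp2 and Yp3 did not differ between the groups by more than its spread (8.21 in pulsed, 9.65 in unpulsed heads, exact permutation p = 0.600). The eIF-4a control had a 3′ minus 5′ difference of 2.96 in pulsed and 3.28 in unpulsed heads (exact permutation p = 0.0571), and actin 3.35 and 3.56 (exact permutation p = 0.114). Array medians (exact permutation p = 0.714) and interquartile ranges (exact permutation p = 0.971) did not differ by more than their spread.

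**Figure D3:**
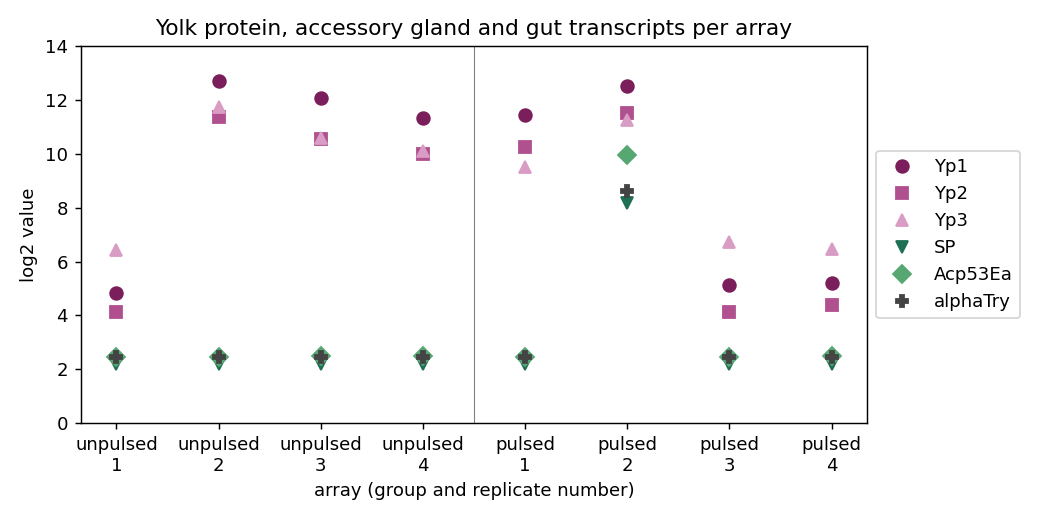
Log2 values of 3 yolk protein genes (Yp1, Yp2, Yp3), 2 accessory gland genes (SP, Acp53Ea) and a gut trypsin gene (alphaTry) on each of the 8 arrays, 1 point per gene and array. SP, Acp53Ea and alphaTry stand at 8.16, 9.94 and 8.60 on pulsed replicate 2 alone, and the yolk protein genes are low on 3 arrays, 1 unpulsed and 2 pulsed.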

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

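In the weighing of foreign RNA on pulsed replicate 2, the 3 tests were chosen after the result was seen. Each quantity here was singled out because 1 array of a group of 4 lay far from its 3 fellows, by the ratio of its gap to the nearest array over the range of the group, with Dixon's 95% critical value as the limit. Of 440 groups of 4 tested, 41 passed it, 9.32%, where chance gives about 1 in 20. Pulsed replicate 2 accounts for 18 of them, unpulsed replicate 3 for 11, and pulsed replicate 3 for 0.

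Pulsed replicate 2 stood apart with transcripts of the male reproductive tract and the gut. Not every transcript high there was confined to it. EbpII and Ebp, at 11.3 and 10.2 there, had highest values of 6.99 and 6.79 among the other 7 arrays, whose means were 3.14 and 2.96. The other arrays can therefore not be taken as free of such RNA. The ratio was 0.999 for the list of testis and accessory gland, at a mean log2 value of 6.29 against 2.46 on the other pulsed arrays, and 0.974 for gut digestive enzymes, at 4.60 against 2.57. Single genes of these lists gave ratios of 0.982 (Mst84Dc), 0.993 (Mst98Ca), 0.996 (Acp76A), 0.997 (Mst98Cb), 0.941 (Jon65Aii), 0.981 (Jon25Bii) and 0.985 (Mal-A2), all with the array highest. Of these, Jon25Bii (2.57 against 2.38) and Mal-A2 (2.35 against 2.12) lay near the floor with small gaps, so their ratios say little. The median correlation of the array with the others, 0.986, was lowest with a ratio of 0.997.

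A candidate explanation for this pattern is RNA of body tissue, from males, in the head sample of pulsed replicate 2. Of 26 measured markers of testis, accessory gland and gut, 19 lay over 1 log2 unit above all 7 other arrays, and the median excess of the 26 over the mean of the other 7 arrays was 3.16. RNA of the female reproductive tract is argued against by 0 of 13 ovary and eggshell markers at that distance. A response to the light pulse is argued against by the other 3 pulsed arrays, where the median of the 26 markers differed from unpulsed arrays by 0.0036. How the tissue entered the sample stays open, and abundant transcripts of it were clear, with Acp53Ea at 9.94, alphaTry at 8.60 and SP at 8.16.

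Other quantities on pulsed replicate 2 were singled out with values near the floor or small gaps. Cp36 (ratio 0.909), bcd (0.948), E(spl)m6-BFM (0.973), TotZ (0.82904) and Xpd (0.933) were lowest there and Cp18 (0.949) highest, all with log2 values under 3. Ugt49B1 was highest at 8.69 (ratio 0.923), and the ecdysone response list was lowest at 6.71 against 6.89 (0.875).

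On unpulsed replicate 3, nrv2 (0.831), Pis (0.867), Pu (0.886) and E(spl)m3-HLH (0.868) were highest of their group. CrebB (0.960), Cyp309a1 (0.956), Cpr47Ee (0.834), Inx2 (0.854) and Obp99b (0.839) were lowest. The fasting and lipid list was lowest there at 8.74 against 9.03 (0.846), and the actin 3′ minus 5′ difference highest at 3.65 against 3.53 (0.951).

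Unpulsed replicate 1 was highest for slmb (0.849), nSyb (0.869) and Xpd (0.888), and lowest for Yp1, at 4.82 against 12.0 (0.82916). Unpulsed replicate 2 was lowest for 5-HT2A (0.876) and highest for Cp38 (0.931). Unpulsed replicate 4 was lowest for cwo, at 9.10 against 9.53 (0.958), and for Ank, at 10.4 against 10.6 (0.931). Pulsed replicate 4 was lowest for cyc, at 6.776 against 7.005 (0.872), for Sgf29 (0.847) and for E(spl)m3-HLH, at 4.49 against 5.31 (0.866). Pulsed replicate 1 was highest for the photolyase and DNA repair list, at 4.01 against 3.91 (0.900).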

How the results depend on the processing

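Values with an added combination of settings, a batch term, a yolk protein covariate or a 3′ to 5′ covariate come from 5 alternatives chosen after seeing the data, and the others were planned. Of the single named genes, 3294 values kept their direction and side of the threshold, 101 kept the direction and passed the threshold newly (96 of them with array weights), and 63 changed sign. Of the pathway lists 471 values were unchanged in that sense, 13 newly passed, 79 no longer passed and 58 changed sign, and of the marker lists 194, 9, 22 and 28. Of the counts, 98 stayed within 1.5 times and 51 did not. The 24 genes with the strongest statistics, chosen for them on these same arrays, kept their sign and an unadjusted p under 0.05 in all 20 refits. The values given here are medians of log2 differences for lists and log2 differences for genes, and except where a reason is stated the cause was not tested. Each group has 4 arrays, which limits the precision of every value, and whether they are separate groups of flies is not stated.

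Quantile normalization left 1 clock gene past the list-alone threshold and called 6 lists, 1 of them a marker list. Eye pigment (-0.10), antimicrobial peptides (0.53), ribosomal proteins (0.021) and respiratory chain (0.029) were no longer called, and UDP-glycosyltransferases (7.2e-04) changed sign. Median-centred arrays called 1 probe set and 1 clock gene. Eye pigment (-0.12), receptors (-0.049) and ribosomal proteins (0.014) lost their call there, and cycling transcripts (-0.0063), cytochromes P450 (-0.011) and proteasome (-0.010) changed sign. Neither scaling moved the median of all probe sets by over 0.1. A pseudocount of 16 left 1 clock gene and 1 marker list.

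The filter on dim probe sets called 1 probe set and 7 lists, 1 of them of markers, with fewer probe sets tested. Eye pigment (-0.12), receptors (-0.085) and ribosomal proteins (0.032) lost their call under it, and UDP-glycosyltransferases (0.031) and fat body markers (0.016) changed sign. The trended and robust spread called 1 probe set. An adjusted p of 0.1 gave 2 probe sets, an unadjusted p of 0.05 gave 902, and asking also for a 1.5-fold change left the count at 0. With the mean of a gene's probe sets, eye pigment (-0.082) and ribosomal proteins (0.027) lost their call, and 1 marker list was called.

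Camera with an estimated correlation and fry's directional test called 0 lists, 0 of them of markers. A higher correlation does not account for every lost call: the estimate for eye pigment was 0.0035, below the preset 0.01. The adjusted p of 0.364 is shared by the core clock, eye pigment, oxidative stress and immune lists through the adjustment, so it does not rank them. Both tests leave the medians as they are and change only the p: core clock genes (-0.20), phototransduction (-0.082), eye pigment (-0.11), oxidative stress (0.11) and antimicrobial peptides (0.54). The same holds for immune recognition (0.14), receptors (-0.035), ribosomal proteins (0.027) and respiratory chain (0.039).

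Array weights called 2936 probe sets, 7 clock genes, 162 list members and 4 marker lists, with 6505 probe sets at an unadjusted p of 0.05. The marker lists were neurons (-0.14), glia (-0.11), antennal and gustatory support cells (-0.061) and female-biased transcripts (-4.83), while gut (0.060) and testis and accessory gland (0.099) lost their call. Newly called were clock kinases and output (-0.042), CREB and calcium signalling (-0.20), EGFR and ERK feedback (-0.082), ion channels (-0.14), ecdysone response (-0.11) and proteasome (0.040). Lists no longer called were eye pigment (-0.022), immune recognition (0.078), ribosomal proteins (0.022) and respiratory chain (0.022). The sign changed for phototransduction (0.0069), DNA repair (0.0096), UDP-glycosyltransferases (0.013), antimicrobial peptides (-0.50, called in this direction), Turandot and JAK-STAT (0.011) and fasting and lipid genes (-0.034). It also changed for Notch targets (0.012), cuticular proteins (0.011), muscle markers (-0.039), haemocyte markers (0.076) and ovary markers (0.011). Single genes that changed sign were kek1 (-0.21), tefu (0.0015), Hsp27 (-0.059), CecB (-0.54), Mtk (-0.46), edin (-0.71) and TotZ (0.011). Others were upd1 (0.0091), E(spl)mbeta-HLH (0.0014), E(spl)m7-HLH (0.0061), E(spl)m6-BFM (0.016), gcm (0.023) and crq (0.053). So were Cp36 (0.011), bcd (0.0088), fit (-0.31), Obp99b (-0.0047) and sxe2 (0.16).

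No pairing of the arrays by replicate number was seen in correlations of deviations, in which probe sets with a large spread weigh most. Arrays with the same number correlated from -0.070 to 0.078 across probe sets, 0 pairs were over 0.1, and 1 array correlated best with its own number. With the replicate number as a block, 0 probe sets were called, the ribosomal list (median 0.027) was no longer called (adjusted p = 0.0926, in a range of 0.00223 to 0.879 over 23 alternatives), and 1 marker list was.

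Leaving out each array in turn gave 0 to 3 clock genes over the list alone, 3 to 15 lists and 0 to 4 marker lists, with 0 probe sets called each time and fewer arrays in the fit. Ranges for lists were -0.083 to -0.036 for clock kinases and output, -0.025 to 0.026 for cycling transcripts and -0.14 to 0.0076 for CREB and calcium signalling. EGFR and ERK feedback ran from -0.018 to 0.041, phototransduction from -0.11 to -0.030, eye pigment from -0.12 to -0.071 and DNA repair from -0.021 to 0.0029. Heat shock proteins ran from -0.028 to 0.056, cytochromes P450 from -0.0068 to 0.015, UDP-glycosyltransferases from -0.0062 to 0.0047 and antimicrobial peptides from 0.25 to 0.79. For fasting and lipid genes the range was -0.014 to 0.041, for neuropeptides -0.025 to 0.045, for ion channels -0.092 to -0.0045 and for receptors -0.15 to -0.0058. Notch targets ran from -0.025 to 7.9e-04, ribosomal proteins from 0.011 to 0.040, respiratory chain from 0.0031 to 0.061 and proteasome from -0.0014 to 0.019. Cuticular proteins ran from -0.0090 to 0.0032, fat body markers from -0.033 to 0.0088, muscle markers from -2.1e-04 to 0.10 and haemocyte markers from -0.060 to 0.033. Ovary markers ran from -0.019 to 0.0012 and male-biased transcripts from -0.056 to 0.043. JNK and AP-1 targets ran from -0.065 to -0.0031, Turandot and JAK-STAT from -0.018 to -0.0020, ecdysone response from -0.10 to -0.0012 and activity-regulated genes from 0.041 to 0.086. Neurons ran from -0.17 to -0.027, glia from -0.046 to -0.012, antennal and gustatory support cells from -0.073 to -0.025 and female-biased transcripts from -2.69 to -0.39. Newly called without unpulsed replicate 3 were clock kinases and output (-0.055), CREB and calcium signalling (-0.14), ion channels (-0.092), proteasome (0.019), neurons (-0.16), glia (-0.043) and antennal support cells (-0.073). Gut markers lost their call when any 1 unpulsed array was left out. Among single genes, Mkp3 ran from -0.12 to 0.011, Cp18 from -0.069 to 0.012 and sxe2 from -0.056 to 0.062.

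The filter on dim probe sets without pulsed replicate 2 called 1 probe set, 0 clock genes and 3 lists, 0 of them of markers, with 532 at an unadjusted p of 0.05. Phototransduction (-0.051), eye pigment (-0.10), antimicrobial peptides (0.37), receptors (-0.070), ribosomal proteins (0.016) and respiratory chain (0.010) were no longer called. EGFR and ERK feedback (0.013), heat shock proteins (0.041), UDP-glycosyltransferases (0.060), fat body markers (0.051) and male-biased transcripts (0.043) changed sign, as did sxe2 (0.043). The trended spread without that array called 1 probe set, 0 clock genes and 5 lists, 0 of them of markers, with 449 at an unadjusted p of 0.05. Activity-regulated genes (0.055) were newly called. Phototransduction (-0.051), antimicrobial peptides (0.37), receptors (-0.040), ribosomal proteins (0.011) and respiratory chain (0.0031) were not. There EGFR and ERK feedback (0.013), heat shock proteins (0.041), UDP-glycosyltransferases (0.0047), cuticular proteins (0.0030), fat body markers (0.0023), ovary markers (5.4e-04), male-biased transcripts (0.043) and sxe2 (0.043) changed sign.

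The batch term for replicate numbers left 0 clock genes and 1 marker list. The yolk protein covariate newly called CREB and calcium signalling (-0.063), and cycling transcripts (-0.0024), fat body markers (0.066), female-biased transcripts (0.11) and male-biased transcripts (0.0089) changed sign. Yp1 (0.052), Yp2 (0.16) and sxe2 (0.0089) did so too, the first pair by construction, since the covariate is made from their own levels.

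The 3′ to 5′ covariate, which moves with the groups and so widens the error, left 0 clock genes, 0 lists and 0 marker lists. No longer called were core clock genes (-0.22), phototransduction (-0.070), eye pigment (-0.080), oxidative stress (0.0069), antimicrobial peptides (0.45), immune recognition (3.2e-04), receptors (-0.21) and ribosomal proteins (0.0083). The sign changed for cytochromes P450 (-0.054), UDP-glycosyltransferases (0.012), Turandot and JAK-STAT (0.011), neuropeptides (-0.045), Notch targets (0.0094), respiratory chain (-0.033) and cuticular proteins (0.010). Among markers it changed for fat body (0.0043), muscle (-0.068), gut (-0.18), testis (-0.39), ovary (0.0059) and male-biased transcripts (0.057). Single genes with a changed sign were Clk (0.056), cwo (0.011), CSN5 (-0.086), wdb (0.045), CG13868 (0.0099), hep (0.20) and Dsor1 (-0.023). Mkp3 (0.046), Pu (0.053), lok (-0.0045), stv (0.018), TotZ (0.013), upd1 (0.025), Lk (-0.024) and Nplp2 (0.051) were others. The same was true of nAChRalpha4 (0.17), Eip93F (0.044), EcR (0.15), E(spl)m6-BFM (0.0067), Rpt4 (-0.076), Inx2 (0.036), gcm (0.0020) and crq (0.11). Of gut and reproductive genes these were Jon65Aii (-0.063), Jon25Bii (-0.011), Mal-A2 (-0.018), Mal-A1 (-0.86), Mst84Dc (-0.43), Mst98Ca (-0.33) and Acp76A (-0.13). Mst98Cb (-0.15), Cp36 (0.0059), bcd (0.012) and sxe2 (0.057) complete them.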

Other observations

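Tests of the core clock genes over the list alone, of array weights and of the trended spread over splits of the arrays were set before their results were seen, and the other tests here were chosen after the result was seen.

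The mean of the yolk protein transcripts Yp1, Yp2 and Yp3 spanned 6.43 log2 units among pulsed and 6.80 among unpulsed arrays, and a response to the light pulse alone is argued against by the smaller of these ranges, 6.43. A large difference in the share of female flies between samples may account for it. The male-biased head transcripts that would then move the other way spanned at most 0.66 log2 units (Cyp4d21), with sxe2 at 0.35 and Obp99b at 0.32. That range decides neither way: a first test on roX1 and roX2 gave no value for want of probe sets, the bounds of 1 and 0.5 log2 units were set when these ranges were known, and Obp99b at about 15 is near the top of the scale. On the low-yolk arrays, unpulsed replicate 1 and pulsed replicates 3 and 4, none of these transcripts exceeded its highest value elsewhere. Cyp4d21 was 11.79 to 11.80 there, inside 11.51 to 12.18 on the others, and sxe2 was lowest of all on unpulsed replicate 1 (11.45). This argues against a large difference in the share of females, as far as their male bias, not measured here, holds. The female-biased fit spanned 0.71 log2 units and went both ways. It was lowest on unpulsed replicate 1 (11.75), with low yolk values, and highest on unpulsed replicate 2 (12.46) and pulsed replicate 2 (12.44), with the highest. Against that, it was at 12.03 and 12.09 on pulsed replicates 3 and 4 with low yolk values and 11.76 on unpulsed replicate 3 with high ones. It is also 1 gene whose bias was not measured here, so it decides neither way. The share of females is thus argued against only by the male-biased transcripts and is not settled. The age or feeding state of the females stays open and was not tested.

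The core clock list was lower in pulsed heads, which may be a response to the light pulse, and technical explanations were set against it. Foreign tissue in pulsed replicate 2 as the whole cause is argued against by the fit without that array, where the median was -0.18 against -0.20, with a camera adjusted p of 0.0114 in a range of 2.5e-04 to 0.364 over 23 alternatives, though with an estimated correlation that fit made no call either (adjusted p = 0.418). RNA integrity cannot be told apart from the pulse, since the 3′ minus 5′ differences move with the groups. With their mean as a covariate the median went from -0.20 (median SE 0.10) to -0.22 (median SE 0.16) and camera's adjusted p to 0.213. The call thus ended with a wider error and not with a smaller median, but members moved both ways. With the covariate vri was at -0.22, cwo at 0.011, Clk at 0.056 and cry at 0.020. On the other side per was at -0.55, tim at -0.41, Pdp1 at -0.25 and cyc at -0.22. A biological effect of the pulse and RNA integrity both stay open.

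Whether chance can be excluded was asked by regrouping the 8 arrays into 4 and 4 in all 35 ways, the real one included. For probe sets past adjusted p 0.05 the real count is 0, which all 35 reach by definition, so that count cannot test chance. The highest other gave 2. In 3 of 35 the smallest adjusted p was at or below the real 0.0611, with 0.0267 the lowest of the others, and in 9 at least 902 probe sets passed an unadjusted p of 0.05. Chance is not excluded for the smallest adjusted p or for the count at an unadjusted p of 0.05. Nor is it for the 11 lists called, reached by 11 splits with a highest other of 15. The 2 clock genes over the list alone were reached by 3 splits, with a highest other of 2, so chance is not excluded there either. The split of replicates 1 and 2 against 3 and 4 gave 3297 probe sets at an unadjusted p of 0.05, with 0 past adjusted p 0.05 and 9 lists called, and the next highest split gave 2017. A count several times the real one can point to a structure of the samples that does not follow the groups, but this split was picked as the highest of 35. Across the groups, deviations of arrays within 1 and 2 or within 3 and 4 did not go together, with 6 of 8 correlations negative (-0.147 to 0.0778). Probe sets with a large spread weigh most in these correlations, and the pairs are not independent. A small shift of many probe sets could escape them, so such a structure is neither shown nor excluded. With that split as a batch term the clock list had an adjusted p of 0.00640.

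With array weights the real split gave 2936 probe sets, the most of the 35 (1 split), with 2522 in the highest other. The next gave 865 and 812, so that large counts under the weights also arise in groupings other than that by the pulse, and in 4 of the 35 splits, not the real one, the weights did not fully converge. With the trended and robust spread the real split was the 1 split with a call (CG10513), with 0 in the others. Taken alone, each of these counts is reached by 1 of 35 splits, but a single call against 0 is little evidence, both settings stand among several tried, and chance is not excluded. The count with array weights also comes from weights between 0.198 and 10.1, in which pulsed replicate 2 had 0.229, pulsed replicate 3 had 6.81 and unpulsed replicate 2 had 10.1. These last 2 arrays carry most of the weight of their groups, and their yolk protein means differ, at 5.33 and 11.9.

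By list, the real split had the smallest camera p of all 35 for core clock genes (5.5e-04, next 0.00108), eye pigment genes (0.0110, next 0.0154) and oxidative stress genes (1.2e-04, next 0.00174), each reached by 1 split. These 3 were looked at because they had been called, and of all 38 lists 3 had their smallest p in the real split, where chance gives 1.09, a number reached by 5 of 35 splits with a highest other of 4. Because 5 of 35 splits reached that number, chance is not excluded for them as a set. The exact permutation test of their mean values gave each p = 0.0286, the smallest that 70 arrangements allow. With 38 lists, 3 lists at that floor cannot pass after adjustment, so their adjusted p of 0.362 decides nothing. For immune recognition 2 splits reached the real p of 1.3e-06, with a lowest other of 8.7e-08, so chance is not excluded. The real p was reached by 7 splits for phototransduction (0.00298, lowest other 1.9e-09), 17 for neurotransmitter receptors (0.00868, 1.4e-08), 15 for antimicrobial peptides (0.00673, 1.7e-13), 16 for ribosomal proteins (0.00508, 4.3e-08) and 20 for the respiratory chain (5.3e-04, 1.4e-09). For the markers it was reached by 24 splits for gut (0.0133, 3.8e-05) and 26 for testis and accessory gland (8.9e-04, 3.7e-08), and chance is not excluded for any of these 7 lists.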
